A study of Canis lupus familiaris with 16 samples.

How the data were processed

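RNA sequencing libraries were analysed from 4 canine hepatocellular carcinoma cell lines, KU-cHCC-005, KU-cHCC-004, KU-cHCC-002 and KU-cHCC-001, which were derived from hepatic tumours of dogs. Each line was given 4 treatments for 24 h: sorafenib at 30 µM, its vehicle dimethyl sulfoxide (DMSO), toceranib at 15 µM, and its vehicle Dulbecco's phosphate-buffered saline (DPBS). Each line contributed 1 library per treatment, 16 libraries in all. Per the labels' protocols, the medium was Advanced DMEM with fetal bovine serum, RNA was taken with Trizol, and libraries were made with the NEBNext Ultra II Directional kit, which keeps strand.

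The authors deposited raw read counts per gene symbol for each library, as whole numbers without normalization. TopHat is the tool listed per the submitters' processing notes. Its version, the read counter, the strand setting of the counter, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Each table held 39954 entries, of which 500 shared 89 symbols. Entries of 1 symbol were summed, which gave 39543 symbols, 28342 of them with at least 1 read. Of the symbols, 22047 start with LOC, and 37336 match the RefSeq gene table of the UU_Cfam_GSD_1.0 assembly, which was used for names alone. Without a stated strand setting or multi-mapping rule, counts of overlapping, antisense and near-identical genes are uncertain. This covers histone genes such as H2BC11 and the mitochondrial transcripts, which have nuclear copies.

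Total counts per library ran from 17055803 to 19917958 with DMSO, 19667162 to 20312123 with sorafenib, 16349457 to 17959057 with DPBS and 12008366 to 21943572 with toceranib. Between 13471 and 15449 genes per library had 10 counts or more. Counts per gene come from reads without molecular identifiers, so counting error alone understates the error of a value.

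Comparisons used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the treatment as group (15515 genes), libraries were scaled by TMM, and robust quasi-likelihood fits held the treatment and the cell line. The 16 libraries shared 1 estimate of the spread, with 9 residual degrees of freedom and a common dispersion of 0.158. The contrasts were sorafenib minus DMSO, toceranib minus DPBS, DPBS minus DMSO, and the difference between the drug effects. The p-values were adjusted by the Benjamini-Hochberg method and called at an adjusted p under 0.05. Fold changes are log2 values with their standard errors (SE). CPM are counts scaled to the TMM library sizes, given as mean ± SD over the 4 lines. A further F-test asked whether a drug effect was equal in the 4 lines. It takes its spread from how DPBS and DMSO differ between lines (3 residual degrees of freedom).

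The cell line entered as a block because libraries with the same number come from the same line, so the labels pair them. Deviations from the treatment means were correlated across genes to check the pairing. Same-line libraries correlated at 0.725 to 0.888 between DMSO and sorafenib, and at 0.538 to 0.794 between DMSO and toceranib, and each of the 4 libraries matched its own line best. Between DMSO and DPBS the same-line values were -0.462 to 0.277, and 2 of 4 libraries matched their own line best, that of KU-cHCC-005 at 0.277 against 0.275 for another line. Between DPBS and toceranib the same-line values were -0.521 to 0.535, and 1 of 4 libraries matched its own line best. The identity of the DPBS libraries was therefore checked with genes at least 4-fold higher or lower in a line than in every other line by the DMSO and sorafenib libraries, on log2(CPM + 0.5). Library pairs were compared by the median ratio of the squared count difference to that of sampling noise alone, over 10799 genes. Libraries keep the names of their labels throughout.

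Lists of genes were fixed for 27 pathways and cell types. They cover the integrated stress response, unfolded protein response chaperones, ERK pathway output, G1/S and DNA replication, G2/M and mitosis, p53 targets, cholesterol synthesis, fatty acid synthesis, and lysosome and autophagy. They also cover NRF2 targets, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrial transcripts, the heat shock response, NF-kappaB and cytokines, the interferon response, YAP and TGF-beta targets, and apoptosis regulators. The others are ribosome biogenesis, aryl hydrocarbon receptor targets, bile acid and drug transport, kinases the drugs are known to inhibit, and markers of hepatocytes, of cholangiocytes and progenitors, of mesenchymal cells, of endothelium and of leukocytes. The 26 lists with 5 or more tested members were tested with camera (preset correlation 0.01, or an estimated correlation) and fry, adjusted over the lists.

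The samples, main fits, lists, most alternatives and the rule for named genes were chosen before the data were examined. Genes are named by that rule if they had an adjusted p under 0.05, a mean of 5 CPM or more over the 16 libraries and the same direction in all 4 lines. The 10 largest increases and the 10 largest decreases of each drug are named, and 3 members with the smallest adjusted p of each called list. The rule also takes the drug target kinases above 5 CPM, 5 genes each way for the drug difference and for DPBS minus DMSO (without the rule on lines), the 5 smallest p between lines, and the top 3 markers per list. Where fewer than 5 genes passed, the 5 with the smallest p are given as not passing. Further members of a list were chosen after their values were seen, as examples. Some genes that the rule names are not reported here, and remain in the fits and lists.

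Alternatives were another normalization (RLE), no filter on low counts, a mean of 5 CPM or more, no cell line block, each line left out, the 8 libraries of a drug and its vehicle alone, the mean of both vehicles as control, a test against a fold of 1.5, and DESeq2 1.42.0. Fits without DPBS libraries, with DMSO as the control of toceranib, or without features listed at 0 were added after the data were seen. The procedures were tested on data simulated from the real means, with 200 changed genes. For sorafenib against DMSO over 15219 genes, 18.5% of 2-fold and 65.9% of 4-fold changes were found in the 16 libraries. In its 8 libraries, over 13654 genes, these shares were 68.6% and 97.3%. For toceranib against DPBS they were 18.4% and 63.4% (15181 genes), for DPBS against DMSO 14.4% and 57.2% (15173 genes), and for the drug difference 0.3% and 41.7% (15208 genes). The simulated DPBS libraries were independent and paired with their labelled lines, unlike the real ones. The shares that involve DPBS thus do not give the power of the real comparisons. The test between lines found 0 of 200 genes changed 4-fold, so it has little power here. Single values were tested with exact permutation tests, over all libraries and, as added after the data were seen, within the labelled lines, in scipy 1.17.1 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9. Enrichment of Gene Ontology terms was not analysed here.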

Results

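The data were gene counts from 16 RNA-seq libraries of 4 canine hepatocellular carcinoma cell lines treated for 24 h with sorafenib (30 µM), toceranib (15 µM) or the vehicle of each, DMSO for sorafenib and DPBS for toceranib. Sorafenib inhibits several protein kinases, receptor tyrosine kinases among them, and toceranib, a drug for dogs, inhibits receptor tyrosine kinases such as KIT and the VEGF and PDGF receptors. Each treatment had 4 libraries, 1 per line, with 12008366 to 21943572 counts per library. The replicates were thus 4 cell lines by their labels, and the edgeR p-value of a gene measures the spread between these libraries. A camera p-value with the preset correlation takes the genes of a list as nearly independent. It rests mainly on the spread between genes, so its size does not measure how far the lines vary. Other splits of the sorafenib and DMSO libraries reached 15 called lists, against 14 in the real grouping. The DPBS libraries formed 2 close pairs, 002 with 005 and 001 with 004, and did not match 4 different lines. The study asked which transcripts each drug changes.

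The lines expressed bile duct and liver progenitor transcripts and few hepatocyte transcripts. In the DMSO libraries of KU-cHCC-002, KU-cHCC-004 and KU-cHCC-005 the bile duct keratins stood at 5470 to 7680 CPM (KRT7) and 2640 to 5090 CPM (KRT19), and the tight junction gene CLDN4 at 338 to 803 CPM. In KU-cHCC-001 they stood at 288, 21.3 and 1.67 CPM, while the mesenchymal genes VIM (6700 CPM against 1340 to 2070) and FN1 (6260 CPM against 450 to 691) were higher there. EPCAM lay at 229 to 313 CPM in all 4 lines. Albumin (ALB) averaged 0.056 ± 0.00335 CPM (SD, n = 4), and the tumour markers AFP and GPC3 reached 14.6 and 8.60 CPM in KU-cHCC-001 and at most 1.05 CPM in the other lines.

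Of the hepatocyte list, 10 of 34 measured markers reached 5 CPM in any DMSO library, led by the transcription factors FOXA2 (27.9 to 113 CPM), FOXA1 (20.3 to 115 CPM) and HNF4A (5.53 to 79.9 CPM). The counts were 13 of 16 for cholangiocyte and progenitor markers and 17 of 25 for mesenchymal markers, among which TAGLN lay at 2.45 to 210 CPM. The mesenchymal count was 15 in KU-cHCC-001 alone and 6 to 8 in each of the other lines. Of 14 endothelial markers 2 reached 5 CPM, led by EGFL7 at 127 CPM in KU-cHCC-001 and at most 9.34 CPM elsewhere, and TIE1 and CLDN5 stayed at or below 3.92 CPM. Of 18 leukocyte markers, CD14 alone reached 5 CPM (11.6 to 84.4 CPM), with CD74 and LAPTM5 at or below 3.92 CPM. With 1 library per line and vehicle, these levels have no test.

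Transcripts that mark a line were absent from some DPBS libraries labelled with it. L1CAM, a neural adhesion molecule, stood at 1260, 529 and 1100 CPM (here without TMM scaling) in the DMSO, sorafenib and toceranib libraries of KU-cHCC-001 but at 1.56 in the DPBS library labelled KU-cHCC-001. LTBP1 and DPYSL3 gave 507 and 437 in DMSO and 1.73 and 0.334 in DPBS. Over 612 genes that were at least 4-fold higher in KU-cHCC-001 than in every other line, the median log2(CPM + 0.5) was 4.05 with DMSO, 3.86 with sorafenib, 3.94 with toceranib and -0.71 with DPBS. The 6 such genes of KU-cHCC-002 stood at 3.16 and 3.04 in the DPBS libraries labelled KU-cHCC-001 and KU-cHCC-004, and at -0.69 in the one labelled KU-cHCC-002. The 23 genes of KU-cHCC-005 stood at 1.91 and 1.83 in the DPBS libraries labelled KU-cHCC-002 and KU-cHCC-005, against 3.52 and 4.02 in its DMSO and sorafenib libraries. The 12 genes lower in KU-cHCC-005 stood at 2.95 in both of those DPBS libraries, against 0.10 and 0.43. The toceranib library of KU-cHCC-005 lay between as well, at 2.39 for the higher and 2.27 for the lower genes. Both libraries labelled KU-cHCC-005 thus matched its DMSO library in part. All values that use DPBS below rest on these labels, and fits without the DPBS libraries in doubt keep the 1 labelled KU-cHCC-005. That library resembles the left-out one labelled KU-cHCC-002 and is itself not free of doubt.

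Some stromal transcripts, chosen after their values were seen from the 25 mesenchymal markers, set the same libraries apart. The collagen gene COL3A1 had 0 CPM in all DMSO and sorafenib libraries, but 72.5 and 80.4 CPM in the DPBS libraries labelled KU-cHCC-002 and KU-cHCC-005, and 51.7 and 6.54 CPM in toceranib of KU-cHCC-005 and KU-cHCC-004. COL1A2 stood at 61.8 and 63.9 CPM in that DPBS pair and 42.6 CPM in toceranib of KU-cHCC-005, against at most 1.68 CPM in any DMSO or sorafenib library. The smooth muscle actin gene ACTA2 stood at 61.0, 62.8 and 108 CPM in these 3 libraries against at most 2.04 CPM. LUM, a proteoglycan of connective tissue, reached 25.5 CPM in DPBS and 22.3 CPM in toceranib of KU-cHCC-005, against 0 CPM in all DMSO and sorafenib libraries. Other markers of the list were highest in KU-cHCC-001, such as SPARC (226 CPM in its DMSO library against 55.8 CPM in DPBS 002), COL5A1 (166 against 37.7 CPM), DES (137 against 2.37 CPM), COL4A1 (87.7 against 1.24 CPM) and THY1 (15.2 against 3.14 CPM).

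**Figure D1:**
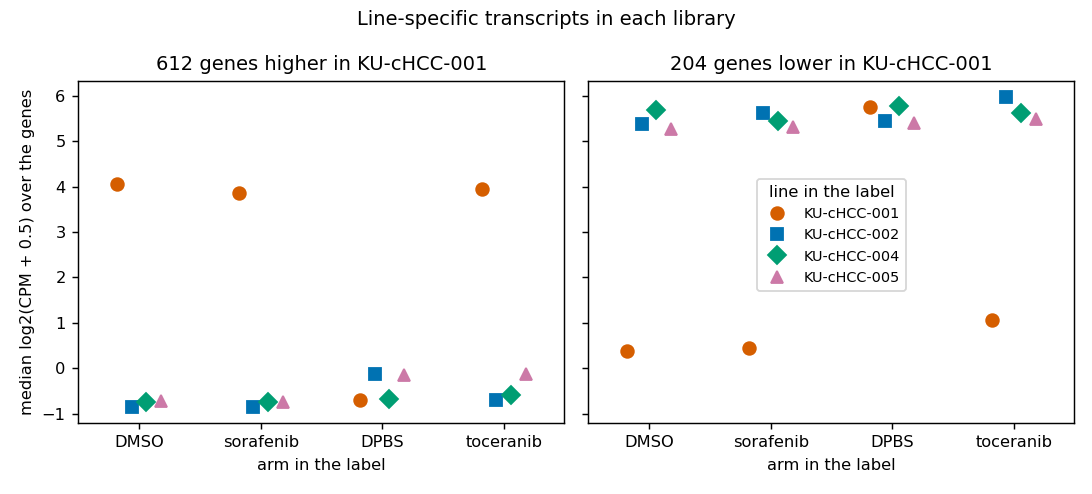
Median log2(CPM + 0.5) of the 612 genes higher and the 204 genes lower in KU-cHCC-001 (defined in its DMSO and sorafenib libraries), for each of the 16 libraries by treatment and labelled line. The DPBS library labelled KU-cHCC-001 lies at -0.71 and 5.76, with the libraries of the other lines.

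Sorafenib against DMSO asked what sorafenib changes in these lines. Of the fixed lists, 20 of 24 genes of sterol synthesis, 12 of 13 mitochondrial transcripts and 24 of 52 mitotic genes fell, and 18 of 36 genes of the integrated stress response rose. The camera calls of these lists held with an estimated correlation in the 16 libraries except that of the mitotic genes (adjusted p = 0.288). In the 8 sorafenib and DMSO libraries none held (adjusted p = 0.184 for sterol synthesis and for mitochondrial transcripts, 0.239 for the stress response and 0.527 for mitotic genes). That fit has 3 residual degrees of freedom, so a test with an estimated correlation can hardly pass there and decides little. GADD45A, a growth arrest gene induced by DNA damage and other stress, rose from 91.6 ± 28.7 to 637 ± 177 CPM (SD, n = 4). LSS, lanosterol synthase, fell from 195 ± 81.7 to 21.4 ± 1.07 CPM, and CLDN2, a tight junction pore protein, fell from 44.0 ± 24.6 to 1.76 ± 1.10 CPM. edgeR called 2034 of 15515 genes at an adjusted p under 0.05, 1059 higher and 975 lower with sorafenib.

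The largest increase was that of IL20RB, a receptor subunit for cytokines of the interleukin 20 family, at a log2 fold change of 5.66 ± 0.72 (SE, edgeR adjusted p = 8.60e-04). OLR1, a receptor for oxidised LDL (4.29 ± 1.10, adjusted p = 0.0270), the stress hormone FGF21 (3.60 ± 0.79, adjusted p = 0.0124) and the lysyl oxidase LOXL4 (3.42) followed. The other named increases were DUSP2 (3.19), GEM (3.02), PLK3 (2.82), GADD45A (2.79 ± 0.30, adjusted p = 3.40e-04), TFPI2 (2.79) and DHRS9 (2.58). After CLDN2 (-4.67 ± 0.41, adjusted p = 1.33e-04), the largest decreases were those of the interferon-induced genes MX1 (-4.62) and ISG15 (-4.54), of HES4 (-3.52) and LRG1 (-3.36), and of the immediate early transcription factor EGR1 (-3.28 ± 0.35, adjusted p = 3.40e-04). The mitochondrial transcripts CYTB (-3.36), ND3 (-3.29) and ND6 (-3.21) and the histone gene H2BC11 (-3.18) completed the 10. MX1 and ISG15 varied most with the line, from -1.23 and -1.06 in KU-cHCC-001 to -6.63 and -6.95 in KU-cHCC-004. In DMSO of KU-cHCC-004 they stood at 985 and 513 CPM, against at most 42.9 and 74.0 CPM in DMSO of the other lines.

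Sterol synthesis had the smallest camera p of the lists. Of 24 tested members, 20 fell and 0 rose (22 and 0 adjusted over the list alone), with a median log2 fold change of -1.45 and per-line medians of -1.63 to -1.32. FDPS (-2.19), LSS (-3.09) and HMGCS1 (-1.82), enzymes of the mevalonate and sterol pathway, led it, and the regulator SREBF2 (-1.31) was among the others. The camera adjusted p was 2.99e-33, and the adjusted p = 0.0125 with an estimated correlation. Of 16 tested genes of fatty acid synthesis 6 fell, among them ACLY (-1.10), AACS (-1.09) and ELOVL6 (-1.32), and 2 rose, ME1 (0.82) and GPAM (0.84); the counts were equal adjusted over the list alone. That list had a camera adjusted p of 8.63e-04 and an adjusted p = 0.180 with an estimated correlation.

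Targets of ATF4 and CHOP in the integrated stress response rose. Of 36 tested members 18 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.93, a camera adjusted p of 7.56e-15 and an adjusted p = 0.0280 with an estimated correlation. SLC3A2, a chain of amino acid transporters, rose from 75.9 ± 8.45 to 321 ± 54.6 CPM, and the phosphatase subunit PPP1R15A (1.71), the tRNA exporter XPOT (1.03), DDIT3 (1.69), TRIB3 (1.13) and ASNS (0.87) rose with it. Of 25 endoplasmic reticulum chaperone and folding genes 9 rose and 0 fell (16 and 0 adjusted over the list alone), with a camera adjusted p of 4.53e-08 and an adjusted p = 0.163 with an estimated correlation. HSPA5, the main chaperone of that compartment, rose by 2.26 ± 0.34 (edgeR adjusted p = 0.00223), SEC24D by 1.09 and HYOU1 by 1.25.

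Of 13 mitochondrially encoded transcripts 12 fell and 0 rose, with the same counts adjusted over the list alone. The median was -1.79, with per-line medians of -2.06 to -1.37, a camera adjusted p of 1.32e-28 and an adjusted p = 0.0280 with an estimated correlation. CYTB went from 2565 ± 320 to 260 ± 106 CPM, and COX2 changed by -2.71. COX1 (-2.14 ± 1.54, edgeR adjusted p = 0.404), lower in 4 of 4 lines, did not pass in the 16 libraries, which include its 0 counts in toceranib of KU-cHCC-004. In the 8 sorafenib and DMSO libraries COX1 passed (-2.21 ± 0.14, edgeR adjusted p = 1.39e-04), and 13 of 13 fell, with an adjusted p = 0.184 for the list with an estimated correlation. Of 43 nuclear-encoded respiratory chain genes 5 fell and 0 rose, both over all genes and adjusted over the list alone, with NDUFA2 (-1.18), SDHA (-0.63) and NDUFB5 (-0.64) first. That list had a median of -0.22, a camera adjusted p of 0.00699 and an adjusted p = 0.671 with an estimated correlation.

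As a share of all counts, mitochondrial transcripts without COX1 took 3.64% ± 0.388 (SD, n = 4) with DMSO and 1.00% ± 0.344 with sorafenib, lower in 4 of 4 lines. With the treatments exchanged within the lines the exact two-sided permutation p was 0.125, the smallest that 16 arrangements allow, so this design cannot pass 0.05. Over all libraries, without regard to line, the exact two-sided permutation p was 0.0286, the smallest that 70 permutations allow, and 0.0429 after Benjamini-Hochberg adjustment over 3 comparisons. The share was 7.0% ± 0.433 with DPBS and 7.38% ± 2.33 with toceranib, a difference of 0.379 percentage points (exact permutation p = 0.875 within lines and 0.83 over all libraries, higher in 3 of 4 labelled lines). DPBS minus DMSO gave 3.36 percentage points (exact permutation p = 0.125 within labelled lines, and 0.0286, adjusted 0.0429, over all libraries; higher in 4 of 4 labelled lines). That test takes the DPBS libraries as 4 independent values although they form 2 close pairs.

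**Figure D2:**
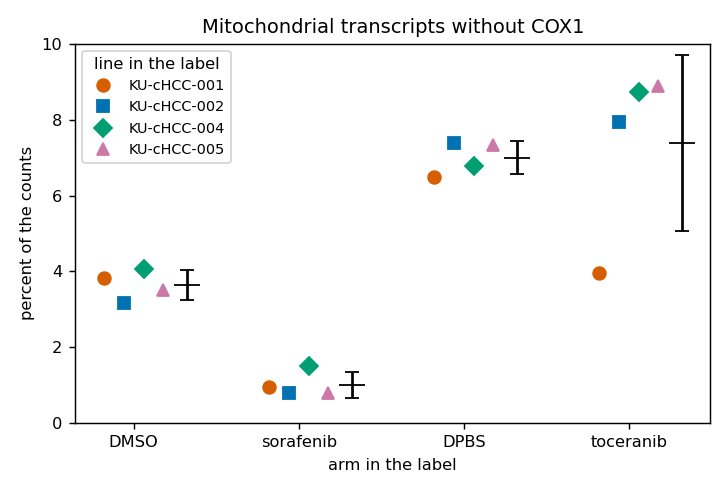
Share of all counts, in percent, taken by mitochondrial transcripts other than COX1, per library and treatment, with black marks for the mean ± SD of 4 libraries. The sorafenib libraries lie at 0.782 to 1.51%, below the DMSO libraries at 3.16 to 4.05%.

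Of 52 genes of G2 and mitosis 24 fell and 0 rose (38 and 0 adjusted over the list alone), with a median of -0.99 and per-line medians from -0.34 in KU-cHCC-004 to -2.15 in KU-cHCC-005. PLK1, a mitotic kinase, went from 131 ± 35.4 to 40.9 ± 20.5 CPM, and HJURP (-2.14), CCNB1 (-1.67) and MKI67 (-2.08) fell too. Of 46 genes of G1/S and DNA replication 10 fell and 0 rose (18 and 0 adjusted over the list alone), among them UNG (-1.69), NASP (-1.29) and RRM2 (-1.99). The camera adjusted p values were 1.00e-16 and 2.44e-08, and with an estimated correlation the adjusted p = 0.288 and the adjusted p = 0.481. Of 22 p53 targets 6 rose and 1 fell (7 and 3 adjusted over the list alone), with GADD45A, CDKN1A (1.97), PLK3, MDM2 (1.29) among those that rose and FDXR (-1.08) the one that fell. This list had a camera adjusted p of 0.0165 and an adjusted p = 0.288 with an estimated correlation.

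Of 21 NRF2 targets 5 rose and 0 fell (7 and 1 adjusted over the list alone), namely HMOX1 (2.57), SLC7A11 (2.34), TXNRD1 (1.64), GSR (1.05) and ME1, with a camera adjusted p of 0.00108 and an adjusted p = 0.163 with an estimated correlation. Of 42 lysosome and autophagy genes 5 rose and 1 fell, also adjusted over the list alone, with WIPI1 (2.23), NPC1 (1.14) and GABARAPL1 (0.92) higher and MAP1LC3B (-0.55) lower; the camera adjusted p was 0.00137 and the adjusted p = 0.481 with an estimated correlation. Of 35 hypoxia and glycolysis genes 8 rose and 1 fell (10 and 2 adjusted over the list alone). VEGFA (1.58), SLC2A1 (1.63) and HK2 (1.10) rose and ANKRD37 (-1.62) fell, with a camera adjusted p of 0.0461 and an adjusted p = 0.617 with an estimated correlation. This last call ended without KU-cHCC-002 (adjusted p = 0.0956), without KU-cHCC-004 (0.0858), without the cell line block (0.0504) and in the 8 sorafenib and DMSO libraries (0.148). Of 9 aryl hydrocarbon receptor targets 2 rose and 0 fell (3 and 0 adjusted over the list alone), CYP1A1 (2.27 ± 0.46, edgeR adjusted p = 0.00917) and TIPARP (1.35), while CYP1B1 (2.13, edgeR adjusted p = 0.0877) passed in the 8 sorafenib and DMSO libraries alone (2.13, adjusted p = 0.00557). The camera adjusted p was 0.0174, and the adjusted p = 0.152 with an estimated correlation.

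Of 34 interferon-stimulated genes 8 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -1.62, a camera adjusted p of 4.29e-07 and an adjusted p = 0.481 with an estimated correlation. The per-line medians were 0.07 in KU-cHCC-001, -0.91 in KU-cHCC-002, -2.82 in KU-cHCC-004 and -1.73 in KU-cHCC-005. IRF9 (-1.66), a mediator of interferon signalling, fell with MX1, which stood at 263 ± 482 CPM with DMSO and 4.29 ± 3.78 CPM with sorafenib.

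The other lists were not called by camera in the 16 libraries. Of 18 transcripts induced by ERK signalling, SPRY4 (1.15), ETV5 (1.28), FOSL1 (1.18) and EPHA2 (1.11) rose and EGR1 and FOS (-1.59) fell (5 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.520, median 0.20, mean -0.015). In the heat shock list (adjusted p = 0.149) DNAJA4 (1.27) and HSP90AA1 (1.02) rose and HSPB8 (-1.64) fell, and among apoptosis regulators (0.584) XIAP (1.12) and BIRC2 (0.50) rose and MCL1 (-0.68) and BMF (-1.30) fell. IL11 (2.0) rose in the list of NF-kappaB and cytokines (0.393), SKIL (1.01) among YAP and TGF-beta targets (0.558), and WDR43 (0.58) and UTP20 (0.75) in ribosome biogenesis (0.661). No gene passed in bile acid and drug transport (0.709, median -0.12, mean 0.33), mesenchymal markers (0.199) or endothelial markers (0.680, median -0.22, test direction up). Among hepatocyte markers (0.0691) FOXA1 (-1.53) fell. Among cholangiocyte and progenitor markers (0.156) CD44 (1.22) rose and 3 fell, among them SOX4 (-1.45) and SPP1 (-3.17). Of 4 tested leukocyte markers, too few for a set test, CD68 (2.40) rose. In the 8 sorafenib and DMSO libraries, a test of the lists added after the data were seen, camera did call the mesenchymal (7 of 11 higher, adjusted p = 0.0116), hepatocyte (6 of 10 lower, 0.0260) and cholangiocyte and progenitor markers (6 of 14 lower and 1 higher, 0.0260). Each had an adjusted p = 0.239 with an estimated correlation.

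Among kinases that the drugs inhibit, 6 transcripts did not pass with sorafenib in the 16 libraries. They were ARAF at 0.38 ± 0.15 (edgeR adjusted p = 0.127), BRAF 0.18, PDGFRA 0.62, FLT4 0.44, FLT1 -0.53 and FGFR1 -0.03. In the 8 sorafenib and DMSO libraries ARAF passed (0.34 ± 0.10, edgeR adjusted p = 0.0273, higher in 4 of 4 lines) and the others did not. The camera adjusted p of the kinase list was 0.320 in the 16 libraries.

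**Figure D3:**
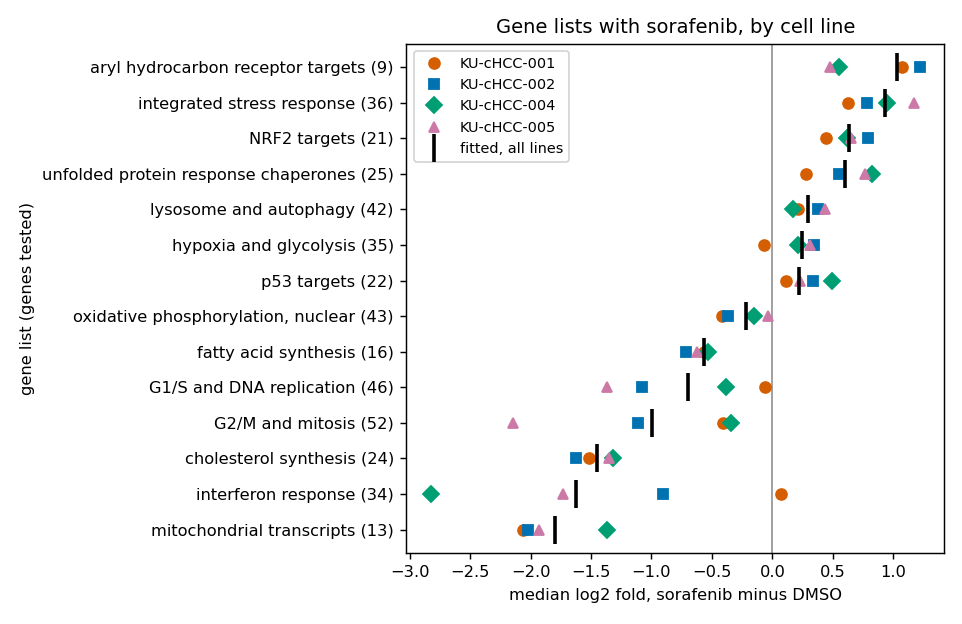
Median log2 fold change, sorafenib minus DMSO, of each gene list called by camera, with a point for each of the 4 cell lines and a bar for the fitted median over all lines. The cholesterol synthesis points lie between -1.63 and -1.32, while the interferon response points run from -2.82 to 0.07.

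The sorafenib count depended on the libraries in the fit. It was 5053 in the 8 sorafenib and DMSO libraries alone, 1259 without the cell line block, 3188 without KU-cHCC-001, 547 without KU-cHCC-002, 188 without KU-cHCC-004 and 130 without KU-cHCC-005. All 1050 increases and all 901 decreases of the 16 libraries that were also tested in the 8 were called there in the same direction. Both fits take the sorafenib effect from the same 8 libraries, and the 8 have the smaller spread. This overlap was thus close to fixed in advance and says little about stability. IL20RB, GADD45A, CLDN2, LRG1, HES4, EGR1, CYTB, ND3, ND6, COX2, LSS, FDPS, HMGCS1, SLC3A2, PPP1R15A, XPOT, SEC24D and HMOX1 passed in each of the 4 fits that left out a line. Further fits, added after the data were seen, left out a line within the 8 libraries. They called 5834 (without KU-cHCC-001), 2523 (KU-cHCC-002), 3067 (KU-cHCC-004) and 2984 (KU-cHCC-005) genes. The tested genes called in all 8 kept their direction, but these fits reuse part of the libraries that selected the genes. The spread in the 16 libraries also rests on the DPBS libraries in doubt (common dispersion 0.158, against 0.0401 in the 8).

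Toceranib against DPBS asked the same of toceranib. No gene passed in edgeR (0 of 15515, with 1875 at an unadjusted p under 0.05), while DESeq2 called 270, 92 higher and 178 lower. The 5 genes with the smallest p, none past the threshold, were CEP350, a centrosomal protein (-0.96 ± 0.14, edgeR adjusted p = 0.113), ILVBL (0.85), ARHGAP5 (-0.98), ATP11B (-0.94) and the translation termination factor ETF1 (-0.79). CEP350 stood at 72.4 ± 4.24 CPM with DPBS and 37.0 ± 0.730 CPM with toceranib (SD, n = 4). The 4 DPBS libraries behind such values form 2 close pairs, so they are not 4 independent lines. COL3A1 averaged 38.2 ± 44.3 CPM with DPBS and 14.6 ± 24.9 CPM with toceranib, and mesenchymal markers were not called (camera adjusted p = 0.575, median -0.79, test direction up).

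Aryl hydrocarbon receptor targets were the one list called also with an estimated correlation and by fry (adjusted p = 0.00932). CYP1A1, the cytochrome P450 that marks activity of this receptor, stood at 64.4 ± 7.76 CPM with DPBS and 307 ± 24.3 CPM with toceranib. It was higher in 4 of 4 labelled lines. Its log2 fold change was 2.31 ± 0.45 (edgeR adjusted p = 0.134), that of CYP1B1 4.64 ± 0.91 (0.134) and that of TIPARP 0.78 ± 0.22 (0.241). By labelled line CYP1B1 gave 7.71 and 6.07 in KU-cHCC-001 and KU-cHCC-004, whose DPBS libraries form a pair. It gave 2.47 and 2.96 in KU-cHCC-002 and KU-cHCC-005, so its size depends on the DPBS libraries in doubt. CYP1A1 ran from 2.08 to 2.53. None of the 9 tested members passed over all genes, and 3 were higher adjusted over the list alone, with a camera adjusted p of 7.73e-05 and an adjusted p = 0.0288 with an estimated correlation. The median was 0.52. With DMSO of the same line as control it was 1.01 (camera adjusted p = 8.54e-05, and adjusted p = 0.558 with an estimated correlation). That fit has 3 residual degrees of freedom, so the test with an estimated correlation decides little there.

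Camera called 7 other lists with medians of -0.57 to 0.25, and none held with an estimated correlation. Nuclear-encoded respiratory chain genes had a median of 0.25 (adjusted p = 7.73e-05, 1 higher adjusted over the list alone), with NDUFA13 0.69, NDUFB9 0.72 and UQCRC1 0.58, and an adjusted p = 0.787 with an estimated correlation. Hypoxia and glycolysis genes had 0.24 (adjusted p = 0.00106, 1 higher adjusted over the list alone; ALDOC 1.5, ANKRD37 0.82, VEGFA 0.64), lysosome and autophagy genes 0.11 (0.0126, 1 higher adjusted over the list alone; GUSB 0.82, NEU1 0.57), and the integrated stress response 0.22 (0.0318; ATF3 0.97, PHGDH 0.91, XPOT -0.39). Interferon-stimulated genes had -0.57 (0.00797, 1 lower adjusted over the list alone; EIF2AK2 -1.52, SAMD9L -1.20, TRIM25 -0.39) and NF-kappaB targets -0.53 (0.0227; BIRC3 -1.53, CXCL8 -1.91, NFKB1 -0.34). For these 5 lists the adjusted p = 0.787 with an estimated correlation. The value of CXCL8 rests largely on KU-cHCC-001 (-4.87, against -1.69 to -0.08 in the other labelled lines). ALDOC gave 2.54 and 1.88 in KU-cHCC-001 and KU-cHCC-004, against 0.64 and 0.35 in KU-cHCC-002 and KU-cHCC-005. ANKRD37 gave 1.76 and 1.21 against 0.03 and -0.07, so both follow the pairs of DPBS libraries. G2/M genes had -0.19 (0.0450; HMMR -1.09, GAS2L3 -1.19, G2E3 -0.68), and an adjusted p = 0.882 with an estimated correlation. With DMSO of the same line as control, added after the data were seen, the integrated stress response turned to a median of -0.303 and was called lower (camera adjusted p = 0.00369, and adjusted p = 0.558 with an estimated correlation), with PHGDH at -0.153. The medians of nuclear-encoded respiratory chain genes (-0.065) and NF-kappaB targets (0.379) changed sign there without a call. The calls of hypoxia (camera adjusted p = 0.245) and lysosome genes (0.260) ended there too. Lists newly called with that control included mitochondrial transcripts (median 0.917, 9.88e-06) and hepatocyte markers (1.02, 0.00369), higher. G1/S genes (-0.301, 2.54e-04) and ribosome biogenesis (-0.27, 0.00409) were called lower. Against DPBS these medians were -0.035, -0.149, -0.124 and -0.068, without a call. The share of mitochondrial transcripts without COX1 was 3.64% with DMSO, 7.0% with DPBS and 7.38% with toceranib. The difference between DMSO and DPBS thus enters these new calls, which do not separate it from the drug. None of these held with an estimated correlation, in a fit with 3 residual degrees of freedom.

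Of the 7 calls against DPBS, 6 ended without single lines, and that of the nuclear-encoded respiratory chain did not. Without KU-cHCC-001 the adjusted p was 0.0678 for hypoxia, 0.0881 for lysosome, 0.513 for NF-kappaB and 0.241 for the integrated stress response; without KU-cHCC-002 it was 0.330 for interferon and 0.166 for lysosome. Without KU-cHCC-004 it was 0.0763 for the integrated stress response and 0.50 for G2/M, and without KU-cHCC-005 it was 0.0728, 0.220 and, for interferon, 0.0800. Among the kinase transcripts, ARAF (0.37), BRAF (-0.45), PDGFRA (1.00), FLT4 (0.16), FLT1 (-0.47) and FGFR1 (0.32) did not pass with toceranib. By labelled line FLT1 ran from -5.81 to 2.60 and PDGFRA from -0.40 to 4.54. Some of these kinases changed direction under other settings, as given below.

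Because of the DPBS labels, other controls were tried. With the mean of both vehicles as control, an alternative chosen before the data were examined, edgeR called 40 genes, 18 higher and 22 lower, with CYP1A1 among them (2.37 ± 0.36, adjusted p = 0.0286). With the DMSO library of the same line as control, added after the data were seen, the counts were 129 genes, 105 higher and 24 lower, and 1755 without KU-cHCC-001. That control differs from the stated vehicle, and the mean of both vehicles includes it.

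**Figure D4:**
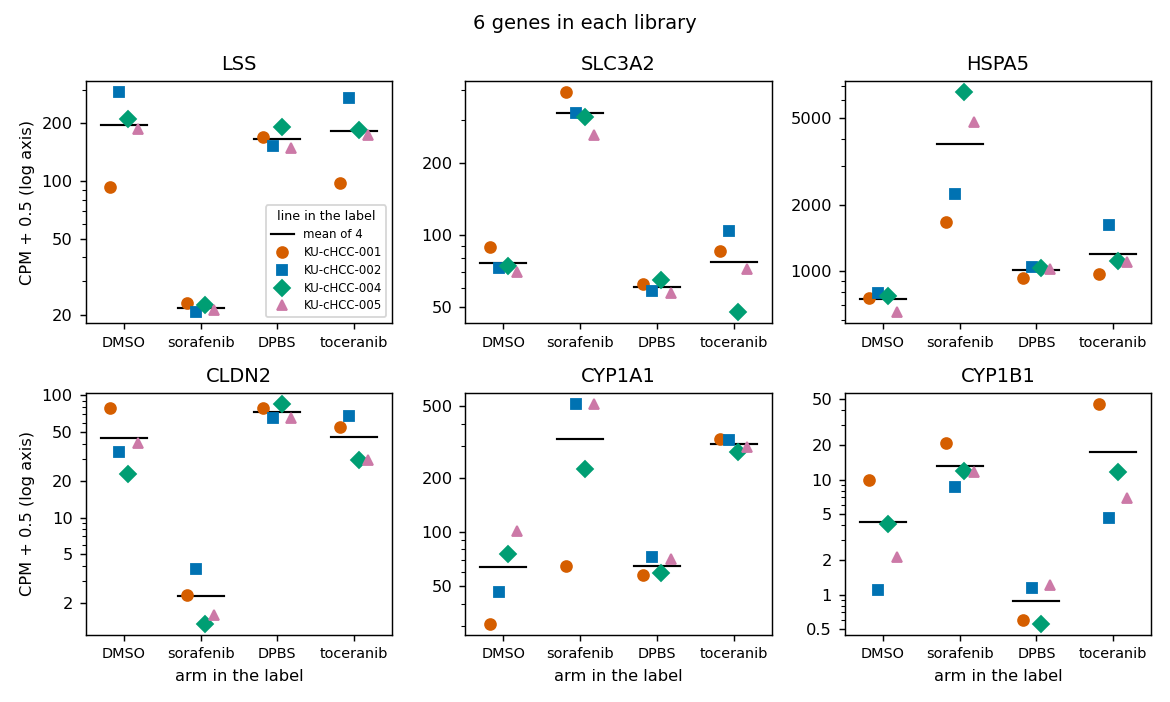
CPM + 0.5 on a log axis of LSS, SLC3A2, HSPA5, CLDN2, CYP1A1 and CYP1B1 in each of the 16 libraries by treatment, with a line for the mean of 4 libraries. CYP1A1 averaged 63.1 CPM with DMSO, 329 with sorafenib, 64.4 with DPBS and 307 with toceranib.

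DPBS against DMSO gave the background of the vehicles. edgeR called 718 of 15515 genes, 451 higher and 267 lower with DPBS. The largest increases were those of the gap junction gene GJB1 (5.97), EPS8L3 (3.92), SLITRK4 (3.49 ± 0.38, adjusted p = 0.00302), the liver transcription factor FOXA3 (3.36) and DNAH10 (3.18). The largest decreases were those of the innate immune gene NLRP12 (-9.96), the transcription factors RUNX3 (-5.07) and NR2F1 (-3.12), GJB5 (-1.99) and S100A4 (-1.96). NLRP12 stood at 81.1 CPM with DMSO and 0 counts with DPBS in the libraries labelled KU-cHCC-001, so its fold rests on that pair. The count was 0, 1 and 2 without KU-cHCC-002, KU-cHCC-004 and KU-cHCC-005 (3149, 3106 and 2502 genes at an unadjusted p under 0.05), 2007 without KU-cHCC-001, 263 without the cell line block and 0 in the 8 vehicle libraries alone (2581). A fit without the DPBS libraries in doubt, added after the data were seen, kept 1 DPBS library, assumed to vary like the other groups. That library, labelled KU-cHCC-005, resembles the left-out one labelled KU-cHCC-002, so the fit is not free of the doubt. The doubt about the labels, and the stromal transcripts of some DPBS libraries (COL3A1 at 0 CPM with DMSO and 38.2 ± 44.3 CPM with DPBS), bear on each of these genes.

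The difference between the drug effects was tested directly, at doses of 30 µM and 15 µM that were not matched. In the sorafenib effect, 18 of 24 sterol synthesis genes, 9 of 13 mitochondrial transcripts and 5 of 52 mitotic genes were lower than in the toceranib effect, and 7 of 36 genes of the integrated stress response were higher. With an estimated correlation the camera call of sterol synthesis held, and those of mitochondrial transcripts (adjusted p = 0.169), mitotic genes (adjusted p = 0.727) and the stress response (adjusted p = 0.262) did not. Between the sorafenib and toceranib libraries of the same line, sterol synthesis had a camera adjusted p = 0.242 with an estimated correlation. That fit has 3 residual degrees of freedom, so such a test can hardly pass there and decides little. edgeR called 1202 of 15515 genes, 694 with a higher and 508 with a lower value in the sorafenib effect. The largest positive differences were those of IL20RB (5.6 ± 0.95, adjusted p = 0.00693), the cystine transporter SLC7A11 (3.24), GEM (3.22), the transferrin receptor TFRC (3.16) and FAM114A1 (3.09). The largest negative ones were those of NLRP12 (-8.62, resting on KU-cHCC-001), LRG1 (-4.35), EGR1 (-4.23), HES4 (-3.84) and CLDN2 (-3.82 ± 0.52, adjusted p = 0.00295). Between the sorafenib and toceranib libraries of the same line, without DPBS, IL20RB was 4.53, SLC7A11 3.23, GEM 3.22, TFRC 2.16 and FAM114A1 2.91. There LRG1 was -3.61, EGR1 -2.65, HES4 -3.43 and CLDN2 -4.79, and NLRP12 was not tested. No vehicle is subtracted in that comparison, so the difference between DMSO and DPBS enters it.

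In cholesterol synthesis 18 of 24 members were lower (20 adjusted over the list alone), with a median difference of -1.56, a camera adjusted p of 7.48e-27 and an adjusted p = 0.0216 with an estimated correlation. Camera also called mitochondrial transcripts (-1.86, 9 of 13 lower, 10 adjusted over the list alone, adjusted p = 4.42e-18), G2/M (-0.81, 5 lower on both counts, 2.31e-07), the integrated stress response (0.66, 7 higher, 10 adjusted over the list alone, 3.74e-06) and nuclear-encoded respiratory chain genes (-0.52, 5 lower on both counts, 1.91e-05). With an estimated correlation these had adjusted p = 0.169, 0.727, 0.262 and 0.727. The last called lists were G1/S (-0.62, 1.81e-04), fatty acid synthesis (-0.85, 3.76e-04), folding genes of the endoplasmic reticulum (0.51, 4.74e-04) and interferon-stimulated genes (-0.80, 0.0235), with adjusted p = 0.789, 0.262, 0.576 and 0.930 with an estimated correlation. Between the sorafenib and toceranib libraries of the same line, a comparison added after the data were seen, the calls of the folding genes (median 0.14) and of the nuclear-encoded respiratory chain genes (-0.20) ended, each with an adjusted p = 0.0695. Newly called in that comparison were NRF2 targets (median 0.955, camera adjusted p = 2.33e-05) and ribosome biogenesis (0.261, 0.0294), higher. Hepatocyte (-1.69, 0.00278) and cholangiocyte and progenitor markers (-1.19, 0.00382) were called lower. None of these held with an estimated correlation, in a fit with 3 residual degrees of freedom. The difference between the vehicles enters that comparison, because no vehicle is subtracted. The interferon call of the drug difference ended without KU-cHCC-004 (adjusted p = 0.838) and without KU-cHCC-005 (0.0605). For aryl hydrocarbon receptor targets the median difference was -0.03 (adjusted p = 0.858).

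The count of genes that differed was 1838 without KU-cHCC-001, 410 without KU-cHCC-002, 12 without KU-cHCC-004, 4 without KU-cHCC-005, and 629 without the cell line block. A fit without the DPBS libraries in doubt, added after the data were seen, had 1 DPBS library left, which is itself not free of doubt. The stromal transcripts of the DPBS and toceranib libraries enter this contrast too. Across 15515 genes, which are not independent replicates, the log2 fold changes of the drugs correlated with Pearson's r = 0.014 and Spearman's rho = -0.068. The comparisons share no libraries. No gene was called in both, since toceranib had 0 calls in edgeR.

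Whether a drug effect differed between the lines could not be resolved. The test takes its spread from DPBS against DMSO by labelled line, and the DPBS labels are in doubt. Toceranib values of KU-cHCC-001 use the DPBS library of that label, which lacked the transcripts of the line. They do not separate the drug from the cell line. edgeR called 0 genes for sorafenib (106 at an unadjusted p under 0.05) and 0 for toceranib (241), and no other tool was run. The genes with the smallest p for sorafenib, none past the threshold, were the linker histone H1-3, KIF20A, ASF1B, ORC1 and PRR11. KIF20A, a mitotic kinesin, had per-line values of -0.85 in KU-cHCC-001, -2.37 in KU-cHCC-002, -1.67 in KU-cHCC-004 and -3.97 in KU-cHCC-005. For toceranib they were COX1, listed at 0 counts in the toceranib library of KU-cHCC-004 (edgeR adjusted p = 0.278), and AADACL4, LRIG3, SCT and LENG8 (-4.25, -2.32, -5.0 and -1.92 in KU-cHCC-001, at most 1.26 in size elsewhere), each with an adjusted p of 1.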

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

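The tests of line labels, of features listed at 0 and of mitochondrial transcripts were chosen only after the results were seen.

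In 155 groups of 4 values (log2 fold changes per line of named genes and lists, library totals and mitochondrial shares), 2 held a line far from the other 3, where chance gives about 1 in 20 groups. EGR1 fell less with sorafenib in KU-cHCC-005 (-2.43) than in the other lines (-3.68 to -3.47). VEGFA stood at 0.35 with sorafenib in KU-cHCC-001 and at 1.96 to 2.09 in the others.

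The DPBS libraries lacked transcripts of their labelled lines or carried those of another, except that the one labelled KU-cHCC-005 carried those of its line in part (median 1.83 against 3.52 with DMSO). An effect of the solvent is argued against by toceranib of KU-cHCC-001, whose vehicle was DPBS and whose 612 line genes kept a median log2(CPM + 0.5) of 3.94. A single library entered more than once is argued against by the closest DPBS pair, which differed by a ratio of 2.38 where sampling noise gives about 1, although DPBS 002 and 005, and DPBS 001 and 004, were far closer than any pair of other treatments (12.9 or more). Libraries of other lines under these labels are consistent with the median of -0.71 in the DPBS library labelled KU-cHCC-001, and stay open as a hypothesis that the tables cannot assign to a step. Stromal transcripts at 0 CPM in all DMSO and sorafenib libraries (COL3A1 at 72.5 and 80.4 CPM in DPBS 002 and 005, and at 51.7 CPM in toceranib of KU-cHCC-005) leave a mix with other cells open. In the comparison of pairs, DPBS 001 and 004 differed over 4-fold from toceranib of KU-cHCC-002 in 8 and 10 genes. From toceranib of their labelled lines they differed in 1013 and 209 genes. These values argue against the labels of both and go with KU-cHCC-002. Which line DPBS 002 and 005 came from is not settled here.

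Features with up to 953060 counts in a library were listed at exactly 0 in others: the mitochondrial gene COX1 in toceranib of KU-cHCC-004, LOC119877774 in all 4 DPBS libraries and in toceranib of KU-cHCC-005, and LOC119877775 in all DPBS and toceranib libraries and in DMSO of KU-cHCC-002 and KU-cHCC-005. A general loss of mitochondrial RNA is argued against for COX1, because the other mitochondrial transcripts of that library had a median log2 difference of 0.37 from DPBS. Whether counting or filtering removed whole features cannot be told apart from other sources, since these features were picked for their zeros and the counting settings are not given in the sources used here. No biological explanation was tested.

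Mitochondrial transcripts were lower with sorafenib in all 4 lines. Library scaling is argued against by their median relative to all genes, which was -1.356 or lower in each line. An equal fall of the whole respiratory chain is argued against by the nuclear-encoded genes, whose median lay 1.572 above that of the mitochondrial ones. RNA quality and transcript selection in the library step were not tested and stay open. An effect of sorafenib on mitochondrial RNA levels may account for the pattern, as a hypothesis found and tested on the same data.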

How the results depend on the processing

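Fits without DPBS libraries, without the 3 features listed at 0, with DMSO as control of toceranib, or between the drugs directly were chosen after the data were seen. The fit of genes in the 8 sorafenib and DMSO libraries was planned, while its own alternatives and its test of lists were added. Fits without the DPBS libraries in doubt keep 1 DPBS library, assumed to vary like the other groups, so their counts say little about stability. That library, labelled KU-cHCC-005, is not free of doubt either. Over all settings the named genes gave 1469 values with the same direction and side of the threshold, 208 that no longer passed, 41 that newly passed and 26 that reversed. Lists gave 212, 77, 0 and 4. RLE scaling and removal of the features listed at 0 changed no call of a named gene. Unless stated, the cause of a change was not tested. The fits with fewer lines have fewer samples.

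The replicate block by cell line, which pairs each drug library with its vehicle by the labels, raised the counts other than that of toceranib. Without it they were 1259 for sorafenib, 0 for toceranib (1374 at an unadjusted p under 0.05), 263 for DPBS against DMSO, 629 for the drug difference, and 71 in the 8 sorafenib and DMSO libraries. Without the block PDGFRA (-0.268) and FGFR1 (0.005) changed direction with sorafenib, the called lists were 13, 6 and 9, and 11 named sorafenib genes lost their call.

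For sorafenib, the 8 libraries alone gave 5053 genes, the mean of both vehicles 3827, a test against a fold of 1.5 gave 276, DESeq2 2924, and fits without all DPBS libraries or without those in doubt 2935 and 2766. Leaving out 1 line gave 130 (KU-cHCC-005) to 3188 (KU-cHCC-001), with 547 without KU-cHCC-002 and 188 without KU-cHCC-004. In the 8 libraries this range was 2523 (KU-cHCC-002) to 5834 (KU-cHCC-001). The common dispersion was 0.158 in the 16 libraries and 0.0401 in those 8. With the mean of both vehicles FLT1 (0.07) and FGFR1 (0.097) changed direction, and FGFR1 ran from -0.09 to 0.019 with 1 line left out.

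For toceranib, the count was 7 without a filter on low counts, 40 with the mean of both vehicles, 270 with DESeq2, 129 with DMSO of the same line as control and 1755 with that control and without KU-cHCC-001. It was 0 or 1 with 1 line left out, the 1 without KU-cHCC-005, and 0 in edgeR without the DPBS libraries in doubt (653 genes at an unadjusted p under 0.05) and with similar DPBS libraries summed (470). With DMSO as control PHGDH (-0.153, and -0.274 without KU-cHCC-001), UQCRC1 (-0.179, -0.359), CXCL8 (1.326, 0.836), NFKB1 (0.159, 0.004), ARAF (-0.461, -0.593) and PDGFRA (-0.217, -0.023) changed direction, as did NEU1 (-0.143) and ANKRD37 (-0.024) without KU-cHCC-001. With the mean of both vehicles ARAF (-0.055) did. Without the DPBS libraries in doubt FLT1 (1.041), FLT4 (-0.135), PDGFRA (-0.095) and FGFR1 (-0.595) did. With 1 line left out FLT1 ran from -1.647 to 0.762 (without KU-cHCC-004) and FLT4 from -0.019 (without KU-cHCC-001) to 0.423. With DPBS as control, edgeR called none of these genes in the 16 libraries. DESeq2 called 13 named toceranib genes that edgeR did not.

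DPBS against DMSO gave 343 genes without a filter, 296 at a mean of 5 CPM or more, 2140 with DESeq2, 4 without the DPBS libraries in doubt, 0 in edgeR in its 8 libraries (2581 at an unadjusted p under 0.05), and 0 (without KU-cHCC-002, 3149 unadjusted) to 2007 (without KU-cHCC-001) with 1 line left out, with 1 without KU-cHCC-004 and 2 without KU-cHCC-005. The drug difference gave 792 without a filter, 2174 with DESeq2, 3949 between the sorafenib and toceranib libraries of the same line, 47 without the DPBS libraries in doubt, and 4 (without KU-cHCC-005) to 1838 (without KU-cHCC-001), with 410 without KU-cHCC-002 and 12 without KU-cHCC-004.

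With an estimated correlation camera called 3 lists for sorafenib, 0 in its 8 libraries (the preset correlation called 16 there), 1 for toceranib and 1 for the drug difference. Fry, which tests whether a list moves on balance, called 11, 1 and 5. Among toceranib lists called against DPBS, medians changed sign with DMSO as control for nuclear-encoded respiratory chain genes (-0.065) and NF-kappaB targets (0.379). That of the integrated stress response did too (-0.303, camera adjusted p = 0.00369, and adjusted p = 0.558 with an estimated correlation). The interferon median of the drug difference ran from -1.45 (without KU-cHCC-001) to -0.281 (without KU-cHCC-004, where the test turned upward).

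Pearson's r between the drug effects was -0.003 at a mean of 5 CPM or more and -0.1 (without KU-cHCC-001) to 0.009 with 1 line left out. With sorafenib taken in KU-cHCC-001 and KU-cHCC-002 and toceranib in the other lines it was -0.105, or -0.102 with DMSO as control. The opposite choice gave 0.097, or -0.038 with DMSO. The smallest library, toceranib of KU-cHCC-005 with 12008366 counts, limits the low genes of that treatment most. The test between lines called 0 genes with RLE scaling and at a mean of 5 CPM or more (104 and 78 genes at an unadjusted p under 0.05 for sorafenib, 246 and 203 for toceranib) in edgeR, and was not run with a line left out.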

Other observations

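With the mean of both vehicles as control, which the DPBS labels affect less because the DMSO libraries carry part of the weight, edgeR called 40 genes for toceranib. CYP1A1 rose by 2.37 ± 0.36 (SE, adjusted p = 0.0286), and the stress transcription factor ATF3 rose by 1.35 (0.0393), with GCKR (1.28), a regulator of glucokinase, MYLIP (1.15), a ubiquitin ligase, KIFC2 (1.06), CLK4 (0.97), the tetraspanin CD63 (0.82) and ILVBL (0.82). The decreases included IDS (-1.47), a lysosomal sulfatase, the kinases MAPK14 (-1.29), AKT2 (-1.14) and MARK4 (-0.76), the serotonin receptor HTR1B (-1.27), AP3S2 (-1.28), EPB41 (-1.25), STAU2 (-1.14) and the glucocorticoid receptor NR3C1 (-1.03). DMSO is not the vehicle of toceranib, so part of the vehicle difference enters these values, and edgeR called none of these genes against DPBS alone. KIFC2 gave 0.594 against DPBS and 1.517 against DMSO, CLK4 0.586 and 1.35, ATF3 0.966 and 1.729, and GCKR 0.948 and 1.621. CYP1A1 gave 2.305 and 2.435, and MYLIP (1.276 and 1.015) and ILVBL (0.85 and 0.791) were larger against DPBS. Each of the genes named here had the same direction in 4 of 4 labelled lines against either vehicle. Against DPBS these are not 4 independent comparisons, because the DPBS libraries form 2 close pairs and did not match 4 different lines. SEC24D, which rose with sorafenib by 1.09, fell by 0.82 with the mean of both vehicles as control.

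The cell lines pair the libraries, so the real grouping is compared with other splits that respect the lines. Counts of splits were chosen after the results were seen, except those for the drug difference over all libraries. For sorafenib against DMSO 8 splits part all 4 lines, too few for a share under 0.05. The real one gave 2034 genes and 14 lists, and the highest of the others 0 genes and 13 lists. For toceranib against DPBS the 8 splits were again too few, with 8 real lists and 10 in the highest other, and for DPBS against DMSO they gave 718 genes and at most 1 in the others. Over all 35 splits, which ignore the lines, 1 gave as many genes for sorafenib (highest other 1) and 4 as many lists (highest other 15), and 1 gave as many genes for DPBS against DMSO (highest other 1). For toceranib 17 of 35 gave as many lists (highest other 12). Its real gene count of 0 is reached by 35 of 35 splits by construction and decides nothing. The highest other had 48 genes and set KU-cHCC-001 and KU-cHCC-004 against the others, the lines whose DPBS libraries resemble each other, which points to a structure of the samples.

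For the drug difference, 50 splits were drawn with the treatments exchanged within each line. The real one alone gave as many genes (1 of 50, 1202 genes, highest other 145), while 26 of 50 gave as many lists as the real 9 (highest other 17). Because the DPBS libraries do not match their labelled lines, these exchanges do not decide about chance. Among 50 splits drawn without regard to line, 1 gave as many genes (highest other 10) and 30 as many lists (highest other 18).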
